A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

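The values are those of the deposited table, which the authors gave as linear signal intensity for each of 9335 probe sets of the YG_S98 array, and how the signals were computed from the probes is not given in the sources used here. The array experiment records, per the labels another kind of file without expression values, were read only for stations, hybridisation times, messages and sample codes. Fluidics runs and sessions were inferred from the stations and times. The 2% trimmed means of the arrays lay between 100.09 and 100.13, so the arrays were used as deposited. The 211 values of 0 and others below the 10th percentile (1.5), 13754 in all, were set to it, values were log2 transformed, 60 control probe sets were left out, and probe sets with a mean below the 25th percentile were left out, which left 6956.

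Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 15 arrays, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of adjusted p < 0.05. The trend was a slope on log2 mannose, any difference was an F-test over the 5 concentrations, and 7 comparisons of 2 concentrations came from the same group means. The 26 gene lists were tested with camera at a preset inter-gene correlation of 0.01, on the 5219 genes with 1 symbol, adjusted over the lists of a comparison, and again with an estimated correlation. Medians and means of lists are of log2 changes, per doubling for the trend. Errors beside log2 changes are standard errors of the fit and those beside signals standard deviations. Where a bracket in the text holds a change and then a bare value, that value is the adjusted p.

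The comparisons, the threshold, the floor, the filter, the lists, the rule for named genes and 17 alternatives were chosen before the data were examined. Added after were the background level, fits without the 5 arrays whose fluidics records were not completed, comparisons within a run, camera for the comparisons other than the trend and 5 against 0.75 g/L, and 10 further lists. Background is 13.5, the 95th percentile of 13 mouse and antisense control probe sets, and a fold against a group whose arrays all lie at or below it is given as a bound.

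Named genes are those with 1 symbol that a rule picked. It always took PMI40, PGI1, RAP1, CDC28 and CLN3, and for the trend the 8 largest rises and 8 largest falls that passed. From each list it took up to 4 members with the smallest adjusted p in the trend. For 5 against 0.75 g/L it took the 10 largest rises and 10 largest falls without overlap between the arrays, for the other comparisons of 2 concentrations 3 and 3, and for any difference the 5 with the smallest adjusted p outside the trend. Of all probe sets 6504 carried 1 symbol, 328 several and 2443 none, and those with several or none were counted but not named.

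The alternatives covered quantile normalization, median scaling, other floors and filters, another variance model, blocks (replicate number, fluidics run, session, station), only the 6 arrays compared, other scales of concentration, each array or concentration left out, another test and an estimated correlation, 40 settings in all. The blocks for fluidics run used duplicateCorrelation where a run held 1 concentration only. Replicate numbers did not pair arrays, since 4 of 30 correlations of same-number arrays between groups exceeded 0.1.

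The code was tested on simulated data with changed and unchanged genes. For the trend 15 of 67 genes changed 1.5-fold, 50 of 67 changed 2-fold and 65 of 66 changed 4-fold were recovered, and for 5 against 0.75 g/L 7 of 67, 43 of 67 and 59 of 66, with 4.4% false among the calls of each. The changed list was called in both and 0 of 25 unchanged lists were. The simulated genes and arrays were independent, without run effects or correlation between genes. False calls of genes and lists under such effects were not tested.

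The labels do not say whether the 3 arrays of a concentration came from separate cultures, and the array records give them a shared sample code, so p-values measure only the spread between arrays. The number of arrays, 3 for each concentration, limits precision. A parent strain, growth rates and residual sugar were not analysed here, nor were probe-level files used here.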

Results

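The 15 arrays measured RNA from a yeast strain without PMI40, the gene of the isomerase that links fructose 6-phosphate to mannose 6-phosphate, so the strain depends on mannose from the medium. Cells grew in aerated batches on 15 g/L glucose with 0.75, 1, 1.5, 3 or 5 g/L initial mannose, 3 arrays for each concentration, and were sampled at 6 h. Signals of the arrays of a group correlated at 0.956 to 0.982 across probe sets, which are not independent replicates. The median signal was 20.1 to 22.1 on the 0.75 g/L arrays and 23.3 to 27.0 on the other 12. The 3'/5' signal ratio of ACT1 was 1.37 to 2.36. That of SPT15 was 2.81 to 6.90, with 4.19 to 5.26 at 0.75 g/L, 3.69, 3.82 and 3.98 at 3 g/L and 4.44, 6.10 and 6.90 at 5 g/L. The 0.75 g/L arrays stood apart on the main axis of variation, which held 39.2% of the variance, and the other concentrations followed each other in order along the next, which held 20.8%.

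**Figure D1:**
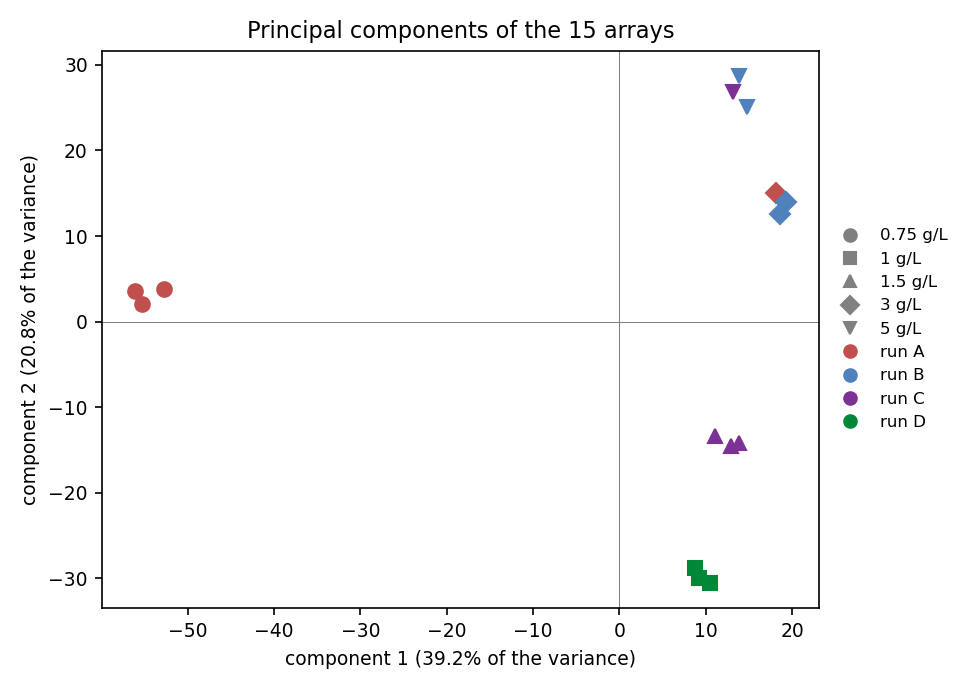
Principal components of the log2 signals of all tested probe sets on the 15 arrays. The horizontal axis (39.2% of variance) and the vertical axis (20.8%) are in component units, the symbol gives initial mannose (g/L) and the colour the fluidics run.

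Fluidics runs were inferred here from the station in the array records and an earlier or later hybridisation time of day (the session). No run or session label was read, and the date was not used. This placed the arrays in 4 runs. Run A held the 3 arrays at 0.75 g/L and 1 array at 3 g/L, run B the other 2 arrays at 3 g/L and 2 at 5 g/L, run C the remaining array at 5 g/L and the 3 at 1.5 g/L, and run D the 3 at 1 g/L. The records of 5 arrays, the 4 of run A and 1 at 5 g/L, described a fluidics run that was not completed. Of the runs with more than 1 concentration, only run A held 0.75 g/L arrays. Comparisons with 0.75 g/L therefore rest for the run on 1 array, 3 g/L replicate 1. That array had the highest CreX-3 control signal, 4020.9 (560.5 to 2119.5 on the others), and the lowest mean correlation with its replicates, 0.960. With the run as a block, slopes of the trend use only differences within runs. Run A gives them through this same array, run C through 1 array at 5 g/L and run B through 2 and 2 arrays. The 1 g/L arrays of run D add nothing to these slopes.

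PMI40 itself gave a signal of 258 ± 21.2 (SD, n = 3) at 0.75 g/L and 241 ± 11.4 at 5 g/L, and its slope per doubling of mannose was 0.06 ± 0.09 log2 (SE; adjusted p = 0.648). Among the 5 concentrations it differed (adjusted p = 0.0303), with the lowest mean, 159 ± 43.7, at 1 g/L. Its signal was 113.1 to 270 over all arrays, above the background of 13.5 and at percentile 79.2 to 88.7 of the probe sets other than controls. Whether the probe set lies inside the deleted part is not given in the sources used here, and no parent strain was measured. What this signal measures is therefore not known, and it cannot be used to check the deletion. PGI1, the glucose 6-phosphate isomerase gene, fell by 0.16 ± 0.05 log2 per doubling (adjusted p = 0.0383), but by only 0.04 ± 0.08 with the fluidics run as a block, where it no longer passed (it did not in 16 of 34 other settings). CLN3, a G1 cyclin tied to cell size, fell by 0.31 ± 0.06 (adjusted p = 0.00294), from 242 ± 47.3 to 139 ± 11.0. RAP1, a regulator of ribosomal protein genes (-0.02 ± 0.10, adjusted p = 0.908), and CDC28, the main cell cycle kinase (-0.06 ± 0.06, adjusted p = 0.541), did not pass.

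Sugar transporter transcripts changed in opposite directions with initial mannose. HXT1, the low-affinity transporter known to be induced by high glucose, rose from 10.2 ± 2.6 (SD, n = 3), within background, at 0.75 g/L to 698 ± 124 at 5 g/L (adjusted p = 9.1e-09). HXT6 and HXT7, high-affinity transporters with nearly identical sequences, fell by 1.08 ± 0.09 and 1.03 ± 0.09 log2 per doubling (adjusted p = 9.6e-07 and 7.63e-07), and HXT7 went from 1884 ± 67.0 to 242 ± 33.8. HXK1, the hexokinase isoform repressed by glucose, fell by 1.22 ± 0.17 (adjusted p = 0.000109), from 2474 ± 157 to 231 ± 24.4. SNO1 and SNZ1, neighbouring genes of vitamin B6 synthesis, rose by 1.91 ± 0.16 and 1.66 ± 0.16 (adjusted p = 6.79e-07 and 1.77e-06).

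DAK2, a dihydroxyacetone kinase, rose from 8.5 ± 4.1 to 386 ± 65.9 (adjusted p = 1.01e-07), and UBC11, a ubiquitin-conjugating enzyme, from 0.7 ± 0.6 to 54.9 ± 8.6 (6.79e-07). PRM5, a pheromone-regulated membrane protein, rose from 5.2 ± 4.1 to 174 ± 14.5 (9.82e-08) and YOR338W from 4.5 ± 2.4 to 70.9 ± 1.9 (1.77e-06). These 4 were within background at 0.75 and 1 g/L. NCA3, a SUN family gene, rose by 2.04 ± 0.12 log2 per doubling (1.28e-08). RGI1, a gene of respiratory growth, fell by 1.12 ± 0.25 (adjusted p = 0.00456) and COX26, a cytochrome oxidase subunit, by 1.12 ± 0.21 (0.00151). OYE3, an NADPH oxidoreductase, fell by 1.05 ± 0.19 (0.0012) and PGM2, the major phosphoglucomutase, by 1.02 ± 0.19 (0.00149). RGI1 and OYE3 had made most of their fall by 1 g/L (118 ± 16.4 and 71.9 ± 19.1), and their slopes without the 0.75 g/L arrays were -0.38 and -0.47. WSC4, of the family of wall stress sensors, fell by 1.06 ± 0.09 (7.6e-07). It was 283 ± 33.4, 306 ± 33.4 and 257 ± 27.1 up to 1.5 g/L and then 83.3 ± 6.2 at 3 and 45.1 ± 5.0 at 5 g/L.

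**Figure D2:**
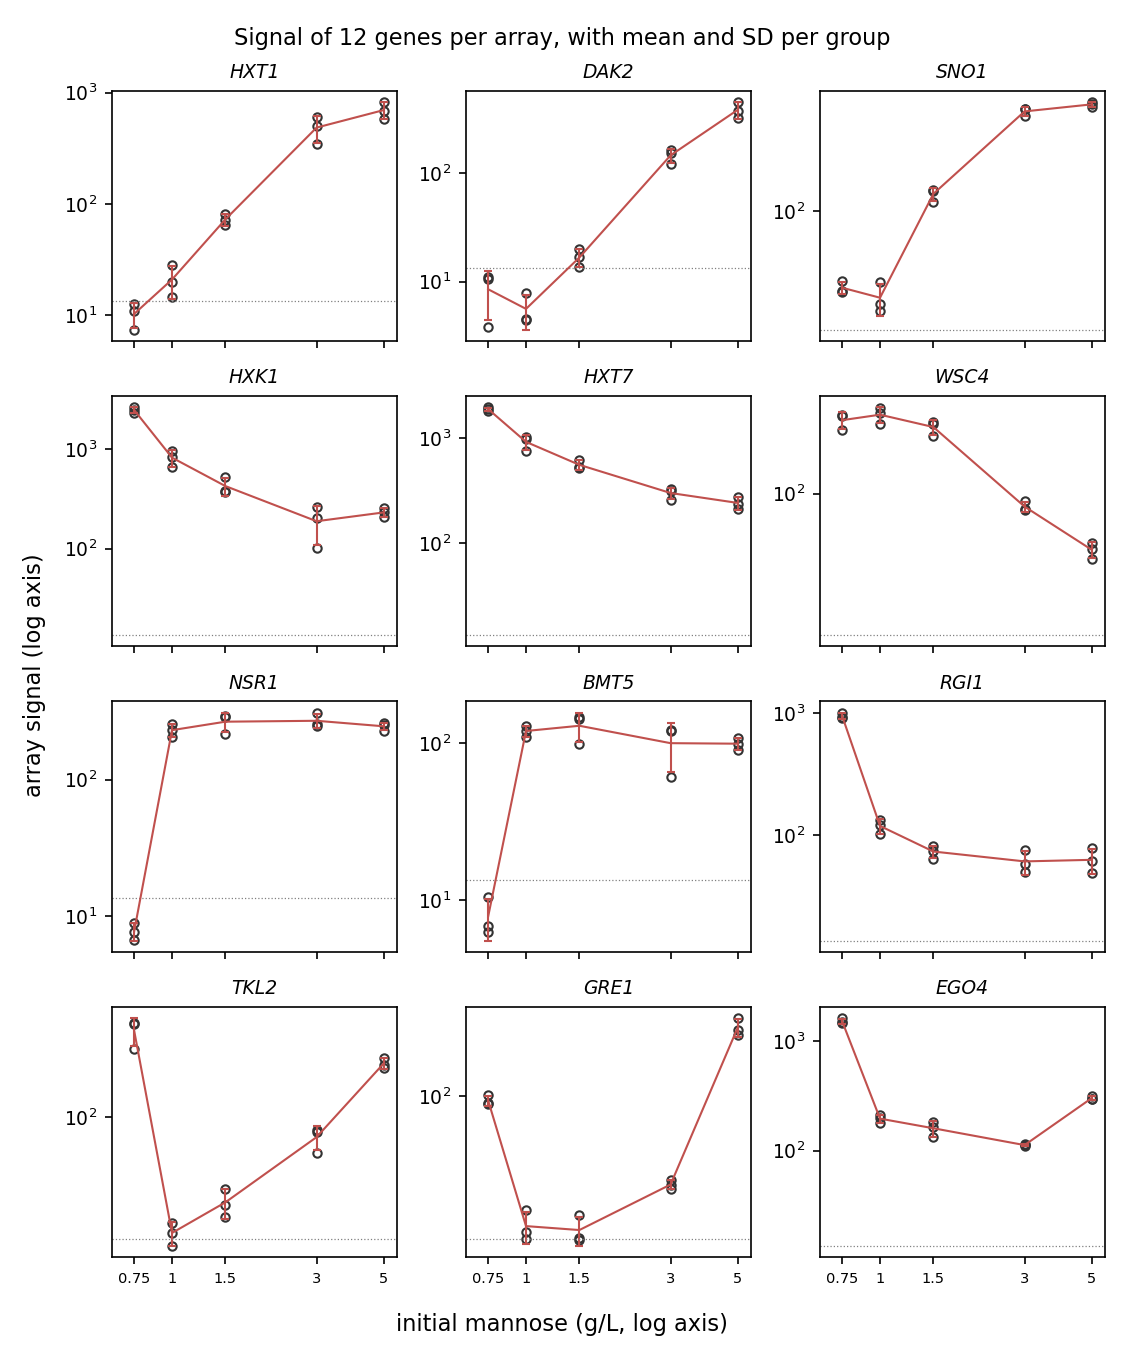
Signals (log axis, intensity) of 12 of the named genes against initial mannose (g/L, log axis), with open circles for arrays and red marks for mean ± SD (n = 3). The dotted line is the background level of 13.5.

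Over all probe sets, 996 rose and 650 fell with mannose, 1646 of 6956 (2555 at unadjusted p < 0.05), and the split was 774 higher and 886 lower after quantile normalization and 592 higher and 1143 lower after median scaling. Without the 0.75 g/L arrays 1868 passed (992 higher, 876 lower). Of the 1646, 964 passed there in the same direction and 0 in the opposite one, and 682 passed only with the 0.75 g/L arrays in the fit. With the fluidics run as a block 875 passed (502 higher, 373 lower).

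Amino acid synthesis was the list with the most members rising. HIS5, of histidine synthesis, rose by 0.60 ± 0.08 log2 per doubling (adjusted p = 6.41e-05) and ILV2, of branched-chain synthesis, by 0.54 ± 0.08 (0.000109). ASN1, asparagine synthetase, rose by 0.53 ± 0.08 (0.000147) and TRP4, of tryptophan synthesis, by 0.51 ± 0.08 (0.000199). Of 41 genes 26 rose, 1 fell and 14 did not pass (28 and 1 adjusted over the list alone). The list shifted up by a median of 0.25 (camera adjusted p = 2.04e-09, and adjusted p = 0.0806 with an estimated correlation). In the sulfur and methionine list SUL1, a sulfate permease, rose from 11.3 ± 1.9 to 76.1 ± 7.4 (adjusted p = 0.000115) and MUP1, a methionine permease, by 0.94 ± 0.18 (0.00146). STR3, a cystathionine beta-lyase, rose by 0.45 ± 0.06 (0.000117) and MET28, a regulator of the pathway, by 0.34 ± 0.06 (0.00148). Of 20 genes 8 rose, 0 fell and 12 did not pass (9 and 0 adjusted over the list alone). The median was 0.18 (camera adjusted p = 0.0045, and adjusted p = 0.413 with an estimated correlation).

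Some glyoxylate cycle and gluconeogenesis genes rose with mannose. ICL1, isocitrate lyase, went from 27.5 ± 4.7 to 293 ± 30.2 (1.25 ± 0.11, adjusted p = 1.5e-06) and MLS1, malate synthase, from 15.3 ± 0.7 to 43.9 ± 6.0 (0.00591). IDP2, the cytosolic isocitrate dehydrogenase, went from 9.4 ± 0.1, within background, to 26.4 ± 0.4 (0.000118) and PCK1, of gluconeogenesis, from 19.4 ± 2.6 to 26.9 ± 2.7 (0.032). Of 8 genes 5 rose, 0 fell and 3 did not pass (5 and 0 adjusted over the list alone). The median was 0.38 (camera adjusted p = 0.0045, and adjusted p = 0.406 with an estimated correlation).

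Most storage carbohydrate genes fell in the trend over all 5 concentrations. TSL1, of the trehalose synthase complex, fell by 0.71 ± 0.12 (adjusted p = 0.000719), GSY1, a glycogen synthase, by 0.69 ± 0.12 (0.000558) and GLC3, the glycogen branching enzyme, by 0.74 ± 0.17 (0.00485). In the trehalose and glycogen list 12 of 17 fell, 0 rose and 5 did not pass (13 and 0 adjusted over the list alone). The median was -0.52 (camera adjusted p = 2.01e-06, and adjusted p = 0.406 with an estimated correlation). In glycolysis GLK1, glucokinase, fell by 0.51 ± 0.10 (0.00201), HXK2, the main hexokinase, by 0.31 ± 0.07 (0.00357) and PFK1, a phosphofructokinase subunit, by 0.15 ± 0.05 (0.0379), which did not pass in 18 of 34 other settings, the run as a block among them (-0.17 ± 0.07). There 6 of 16 fell, 0 rose and 10 did not pass (7 and 0 adjusted over the list alone). The median was -0.13 (camera adjusted p = 0.000575, and adjusted p = 0.223 with an estimated correlation).

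In the pentose phosphate pathway the lactonase genes SOL4 and SOL3 fell by 0.75 ± 0.19 and 0.36 ± 0.11 (adjusted p = 0.0104 and 0.0211). GND1, the major phosphogluconate dehydrogenase, fell by 0.34 ± 0.09 (0.0137) and TAL1, transaldolase, by 0.22 ± 0.06 (0.0149). These were 4 of 10, with 0 higher and 6 not passing (4 and 0 adjusted over the list alone). The median was -0.19 (camera adjusted p = 0.044, and adjusted p = 0.223 with an estimated correlation). In the general stress response SOD2, mitochondrial superoxide dismutase, fell by 0.47 ± 0.09 (0.00123) and HSP26, a small heat shock protein, by 0.50 ± 0.12 (0.00851). TFS1, a carboxypeptidase Y inhibitor, fell by 0.59 ± 0.19 (0.0309), while SSA3, an HSP70 chaperone, rose by 0.44 ± 0.13 (0.0274). In that list 4 of 18 fell, 1 rose and 13 did not pass (4 and 1 adjusted over the list alone). Its median was -0.17 (camera adjusted p = 0.0187, and adjusted p = 0.537 with an estimated correlation).

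In the ribosome biogenesis list IMP4, of the small subunit processome, rose from 18.9 ± 0.9 to 99.3 ± 16.9 (adjusted p = 0.0084) and RLP7, of large subunit assembly, from 15.6 ± 1.3 to 86.6 ± 17.5 (0.0227). EBP2, of pre-rRNA processing, rose from 17.8 ± 3.0 to 97.1 ± 4.9 (0.0251) and NOC4, of 40S maturation, from 5.8 ± 1.8, within background, to 39.4 ± 1.5 (0.0179). These genes were already at 70.9 ± 12.6, 70.0 ± 7.1, 92.7 ± 17.9 and 32.5 ± 2.6 at 1 g/L. Of 35 genes 12 rose, 0 fell and 23 did not pass (25 and 0 adjusted over the list alone). The median was 0.54 (camera adjusted p = 2.01e-06, and adjusted p = 0.517 with an estimated correlation). Of 137 cytosolic ribosomal protein genes listed 80 were tested. RPL22B, of the large subunit, rose (0.42 ± 0.11, adjusted p = 0.0157), 0 fell and 79 did not pass (0 and 0 adjusted over the list alone). The list had a median of 0.00, a mean of 0.01 and a camera direction of down (adjusted p = 0.66), and its median was 0.06 after quantile normalization and -0.07 after median scaling. RPS15 (-0.22 ± 0.13, 0.247), RPS14B (0.23 ± 0.15, 0.293) and RPS26B (0.24 ± 0.16, 0.307), of the small subunit, did not pass.

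PSA1, which makes GDP-mannose, fell by 0.29 ± 0.09 log2 per doubling (adjusted p = 0.0257) and OCH1, which starts outer chains, by 0.31 ± 0.07 (0.00496). PMT4, an O-mannosyltransferase, fell by 0.26 ± 0.09 (0.0393) and DPM1, dolichol phosphate mannose synthase, by 0.18 ± 0.06 (0.0405). PMT4 did not pass in 17 of 34 other settings, the run as a block among them (-0.30 ± 0.11), and DPM1 in 14 of 34. PSA1 was highest at 1 g/L (1607 ± 204, against 964 ± 142 at 0.75 and 681 ± 55.1 at 5 g/L). In the list of GDP-mannose and mannosylation 4 of 28 fell, 1 rose and 23 did not pass (1 and 0 adjusted over the list alone). The median was -0.09 (camera adjusted p = 0.0205, and adjusted p = 0.413 with an estimated correlation).

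With the fluidics run as a block the medians were 0.25 for amino acid synthesis, 0.16 for sulfur and methionine, 0.37 for glyoxylate, -0.57 for trehalose and glycogen, -0.16 for GDP-mannose and 0.47 for ribosome biogenesis. For glycolysis, pentose phosphate and stress they were -0.01, -0.19 and -0.20, and these 3 lists no longer passed. That of cytosolic ribosomal proteins was 0.10, and this list passed upward there (adjusted p = 0.00631). The 3 lists also lost the call after quantile normalization, and passed in 32, 25 and 26 of 34 other settings.

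In 4 lists of glycosylation and the wall, members passed without their list. SEC59, dolichol kinase, rose by 0.25 ± 0.06 (adjusted p = 0.0103), and SWP1, of oligosaccharyl transferase, fell by 0.19 ± 0.06 (0.0266). ALG8 and ALG13, of lipid-linked oligosaccharide synthesis, fell by 0.16 ± 0.05 and 0.28 ± 0.09 (0.0274 and 0.0296). N-glycosylation had 1 higher, 4 lower and 17 not passing of 22 (1 and 4 adjusted over the list alone, camera adjusted p = 0.0771). PDI1, protein disulfide isomerase, fell by 0.22 ± 0.05 (0.00456), SIL1, a nucleotide exchange factor, by 0.29 ± 0.07 (0.00981) and MPD1, a PDI1 relative, by 0.38 ± 0.11 (0.0204). EUG1, another relative, did not pass (-0.26 ± 0.11, 0.0846). The unfolded protein response had 0 higher, 3 lower and 13 not passing of 16 (0 and 3 adjusted over the list alone, camera adjusted p = 0.23).

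CWP1, a wall mannoprotein, fell from 1123 ± 90.1 to 230 ± 29.0 (-0.93 ± 0.10, adjusted p = 5.36e-06), and TIP1, another, rose from 290 ± 19.3 to 1094 ± 114 (0.88 ± 0.10, 9.29e-06). PIR1 and SED1, also wall proteins, fell by 0.28 ± 0.05 and 0.33 ± 0.07 (0.00173 and 0.00449). The cell wall list had 1 higher, 6 lower and 13 not passing of 20 (2 and 6 adjusted over the list alone, camera adjusted p = 0.0714). GNA1, of UDP-GlcNAc synthesis, fell by 0.41 ± 0.07 (0.000365), CHS2, the septum chitin synthase, by 0.40 ± 0.07 (0.00109) and SCW4, a wall glucanase-like protein, by 0.27 ± 0.05 (0.00201). CHS3, the main chitin synthase, rose by 0.39 ± 0.08 (0.00275). Glucan and chitin synthesis had 3 higher, 4 lower and 15 not passing of 22 (5 and 4 adjusted over the list alone). Its median and mean were 0.00 and the camera direction down (adjusted p = 0.506).

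In the cell cycle list CLB1, a B-type cyclin, fell by 0.80 ± 0.11 (adjusted p = 8.52e-05), SWI5, a late mitotic activator, by 0.50 ± 0.08 (0.00055), and CLN3 as above. CLB2, another B-type cyclin, did not pass (-0.19 ± 0.08, 0.101). Of 20 genes 0 rose, 3 fell and 17 did not pass (0 and 3 adjusted over the list alone, camera adjusted p = 0.0714). In the TCA cycle list PYC1, pyruvate carboxylase, rose by 0.37 ± 0.07 (0.000908) and MDH1, malate dehydrogenase, fell by 0.36 ± 0.07 (0.00145). LAT1, of pyruvate dehydrogenase, fell by 0.31 ± 0.07 (0.004) and LSC2, of succinyl-CoA ligase, by 0.28 ± 0.08 (0.021). Of 21 genes 1 rose, 6 fell and 14 did not pass (2 and 6 adjusted over the list alone, camera adjusted p = 0.0523).

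HXT5, a transporter of slow growth, was 39.4 ± 2.4 at 0.75 g/L, 12.7 ± 0.9, within background, at 1 g/L and 192 ± 20.5 at 5 g/L (trend adjusted p = 0.0024). In hexose transport 4 rose, 3 fell and 3 of 10 did not pass (4 and 3 adjusted over the list alone). The median was -0.02, the mean 0.23 and the camera direction down (adjusted p = 0.809). ADH3, the mitochondrial alcohol dehydrogenase, fell by 0.22 ± 0.06 (0.0151). ADH1, its main cytosolic isoform (-0.15 ± 0.06, 0.0864), ALD5, an aldehyde dehydrogenase (0.17 ± 0.07, 0.0907), and PDC1, pyruvate decarboxylase (-0.18 ± 0.08, 0.122), did not pass. For ethanol and acetate 0 rose, 1 fell and 14 of 15 did not pass (0 and 1 adjusted over the list alone, camera adjusted p = 0.147).

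Among the nutrient lists, ARN1 and ENB1, siderophore transporters, rose by 0.63 ± 0.10 and 0.39 ± 0.07 (adjusted p = 0.000493 and 0.000638). SIT1, another, rose from 9.1 ± 0.3 to 14.5 ± 1.3 (0.0365) and FRE1, a ferric reductase, from 9.0 ± 3.0 to 23.5 ± 2.2 (0.00226), both from background. SIT1 did not pass in 18 of 33 other settings, the run as a block among them (0.22 ± 0.07 before and 0.16 ± 0.11 with it). Of 11 iron uptake genes 4 rose, 0 fell and 7 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.0739). PHO8, vacuolar phosphatase, rose by 0.24 ± 0.06 (0.0104), PHO3, an acid phosphatase, from 8.7 ± 1.5, within background, to 21.6 ± 1.1 (0.0134) and PHO89, a phosphate transporter, from 13.0 ± 3.6 to 19.4 ± 0.8 (0.0447). PHO89 did not pass in 24 of 33 other settings, the run as a block among them (0.27 ± 0.09 before and 0.27 ± 0.16 with it), and PHO5, another acid phosphatase, did not pass (0.16 ± 0.06, 0.0851). Of 11 phosphate genes 3 rose, 0 fell and 8 did not pass (3 and 0 adjusted over the list alone, camera adjusted p = 0.556). ERG28, a scaffold of sterol synthesis, and ERG26, a sterol dehydrogenase, fell by 0.42 ± 0.05 and 0.26 ± 0.06 (6.64e-05 and 0.00733). ERG7, lanosterol synthase, rose by 0.24 ± 0.08 (0.0308), and ERG20, farnesyl diphosphate synthase, did not pass (-0.15 ± 0.06, 0.0749). Ergosterol synthesis had 1 higher, 2 lower and 20 not passing of 23 (1 and 2 adjusted over the list alone), with a median of 0.00 and a mean of -0.01 (camera adjusted p = 0.506).

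COX5B, the low-oxygen cytochrome oxidase subunit, fell by 0.54 ± 0.09 (adjusted p = 0.000349) and HEM13, of heme synthesis, from 16.7 ± 5.2 to 10.3 ± 1.4, within background (0.0175). ROX1, the repressor of such genes, rose by 0.43 ± 0.10 (0.00728), and TIR4, a wall protein of anaerobic cells, did not pass (-0.21 ± 0.08, 0.0655). The low-oxygen list had 1 higher, 2 lower and 5 not passing of 8 (1 and 4 adjusted over the list alone, camera adjusted p = 0.0714). MFA1, a mating pheromone, rose by 0.59 ± 0.07 (2.34e-05) and BAR1, a pheromone protease, by 0.37 ± 0.07 (0.00123). STE3, a pheromone receptor, went from 11.0 ± 3.6 to 21.9 ± 2.6 (0.0025), and SAG1, an agglutinin, rose by 0.32 ± 0.10 (0.0327). Of 9 mating-type-specific genes 4 rose, 0 fell and 5 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.0739).

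None of 29 respiratory chain, 7 glycerol and 4 galactose genes passed, also when adjusted over the list alone (camera adjusted p = 0.0926, 0.809 and 1). The glycerol list had a median of 0.06, a mean of -0.02 and a camera direction of down. CYT1, cytochrome c1 (-0.15 ± 0.06, 0.0864), RIP1, the Rieske protein (-0.13 ± 0.05, 0.0876), COX9 (0.16 ± 0.07, 0.104) and COX5A (0.12 ± 0.06, 0.172), of cytochrome oxidase, were nearest in the respiratory chain. GPP1, glycerol phosphatase (0.15 ± 0.06, 0.0705), GPD1, glycerol phosphate dehydrogenase (-0.23 ± 0.10, 0.0945), GUT2, its mitochondrial counterpart (-0.27 ± 0.13, 0.158) and FPS1, the glycerol channel (0.13 ± 0.08, 0.244), were nearest for glycerol. GAL80, the galactose repressor, did not pass either (-0.05 ± 0.08, 0.728). GAL7 and GAL10, of galactose use, were within background throughout (0.688 and 0.712) and GAL4, their activator, at 0.75 to 3 g/L (0.946). After median scaling the trend medians of the galactose, glycerol and phosphate lists changed sign, to -0.03, -0.02 and -0.01.

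Slopes with the fluidics run as a block rest on differences within runs, in run A on 1 array at 3 g/L. Other genes named for the trend that no longer passed with this block had these slopes there. Of the carbon and energy genes they were COX26 (-0.97 ± 0.31), HXK2 (-0.20 ± 0.07), ADH3 (-0.13 ± 0.08), SOL4 (-0.81 ± 0.25), GND1 (-0.27 ± 0.09), TAL1 (-0.18 ± 0.09), LAT1 (-0.21 ± 0.09), LSC2 (-0.21 ± 0.14) and PCK1 (0.23 ± 0.13). For glycosylation and the wall they were PSA1 (-0.24 ± 0.10), SEC59 (0.18 ± 0.10), SWP1 (-0.21 ± 0.07), ALG8 (-0.21 ± 0.08), PDI1 (-0.20 ± 0.07), PIR1 (-0.28 ± 0.09) and SED1 (-0.36 ± 0.11). For ribosomes and stress they were IMP4 (0.58 ± 0.18), EBP2 (0.54 ± 0.17), RPL22B (0.47 ± 0.15), HSP26 (-0.54 ± 0.19), SSA3 (0.61 ± 0.21) and TFS1 (-0.63 ± 0.24), with no call for SSA3 in 9 of 33 and for TFS1 in 11 of 34 other settings. The rest were PHO8 (0.20 ± 0.08), PHO3 (0.25 ± 0.12), MET28 (0.30 ± 0.10), ENB1 (0.23 ± 0.10), FRE1 (0.37 ± 0.12), ERG7 (0.26 ± 0.10), ROX1 (0.40 ± 0.16), HEM13 (-0.26 ± 0.13), BAR1 (0.22 ± 0.10) and STE3 (0.25 ± 0.13). PCK1 did not pass in 11 of 33 other settings, ERG7 in 14 of 34 and SAG1 in 10 of 33.

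The trend without the 0.75 g/L arrays was tested with camera after the results were seen. Cytosolic ribosomal protein genes were lower in it, 48 of 80, with 0 higher and 32 not passing (60 and 0 adjusted over the list alone). Their median was -0.24 (adjusted p = 1.55e-13, and adjusted p = 0.303 with an estimated correlation). Of cell cycle genes 12 were lower, 0 higher and 8 not passing (12 and 0 adjusted over the list alone). Their median was -0.25 (adjusted p = 0.000116, and adjusted p = 0.111 with an estimated correlation). Amino acid synthesis had 23 higher, 1 lower and 17 not passing (25 and 1 adjusted over the list alone). The median was 0.23 (adjusted p = 1.2e-07, and adjusted p = 0.111 with an estimated correlation). Glyoxylate had 6 higher, 0 lower and 2 not passing (7 and 0 adjusted over the list alone). Its median was 0.71 (adjusted p = 3.36e-06, and adjusted p = 0.111 with an estimated correlation).

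General stress was higher in this trend, with 8 higher, 2 lower and 8 not passing (10 and 2 adjusted over the list alone). Its median was 0.23 (camera adjusted p = 0.024, and adjusted p = 0.416 with an estimated correlation). GDP-mannose had 0 higher, 9 lower and 19 not passing (0 and 12 adjusted over the list alone). The median was -0.15 (adjusted p = 0.00192, and adjusted p = 0.324 with an estimated correlation). Glycolysis had 0 higher, 5 lower and 11 not passing (0 and 5 adjusted over the list alone). Its median was -0.12 (adjusted p = 0.0273, and adjusted p = 0.406 with an estimated correlation). Ergosterol had 0 higher, 8 lower and 15 not passing (0 and 9 adjusted over the list alone). The median was -0.10 (adjusted p = 0.0209, and adjusted p = 0.239 with an estimated correlation).

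Of the lists that passed with all 15 arrays, 4 did not pass in this trend. Ribosome biogenesis had 0 higher, 2 lower and 33 not passing (0 and 2 adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.386). Trehalose and glycogen had 1 higher, 4 lower and 12 not passing (1 and 4 adjusted over the list alone), with a median of -0.12 (0.139). Sulfur and methionine had 5 higher, 2 lower and 13 not passing (5 and 2 adjusted over the list alone), with a median of 0.06 (0.309). The pentose phosphate pathway had 1 higher, 2 lower and 7 not passing (1 and 2 adjusted over the list alone), with a median of -0.13 (0.166).

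At 5 against 0.75 g/L HXT1 rose at least 51.2-fold (fitted 6.11 ± 0.27 log2, n = 3 and 3, adjusted p = 3.18e-09), with 0.75 g/L within background. DAK2 rose at least 28.3-fold (5.65 ± 0.36, 5.71e-08) and NSR1, a nucleolar protein of pre-rRNA processing, at least 18.2-fold (5.00 ± 0.17, 3.74e-10). NCA3 rose 30.1-fold (4.91 ± 0.22, 2.81e-09) and SNO1 22.3-fold (4.48 ± 0.18, 1.38e-09). PRM5 rose at least 12.8-fold (5.35 ± 0.46, 8.22e-07), YOR338W at least 5.25-fold (4.16 ± 0.49, 1.37e-05) and ARX1, an export factor of the large ribosomal subunit, at least 4.17-fold (4.23 ± 0.35, 6.06e-07). UBC11 rose at least 4.03-fold (5.18 ± 0.28, 2.5e-08) and SPS1, a sporulation kinase, at least 3.45-fold (4.23 ± 0.51, 1.89e-05). RGI1 fell 15.5-fold (-3.96 ± 0.20, adjusted p = 1.3e-08), OYE3 13.5-fold (-3.76 ± 0.20, 1.55e-08) and GPH1, glycogen phosphorylase, 11.6-fold (-3.54 ± 0.23, 8.03e-08). HXK1 fell 10.7-fold (-3.42 ± 0.28, 5.12e-07), PGM2 9.50-fold (-3.25 ± 0.31, 2.26e-06) and COX26 9.17-fold (-3.20 ± 0.29, 1.09e-06). HXT6 fell 8.73-fold (-3.13 ± 0.20, 5.71e-08) and HXT7 7.82-fold (-2.97 ± 0.17, 2.88e-08). GAD1, glutamate decarboxylase, fell 8.58-fold (-3.10 ± 0.17, 1.95e-08) and YOR186W at least 3.05-fold (-2.97 ± 0.33, 7.15e-06).

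In all, 1545 probe sets were higher and 928 lower, 2473 together (3128 at unadjusted p < 0.05), of which 797 and 371 changed at least 2-fold. No overlap between the 6 arrays was found for 51.1% of probe sets, where chance gives 10%. Here and in the comparisons below, that 10% holds only for independent arrays. Those of a concentration share a sample code and mostly a fluidics run, so a share above 10% need not come from mannose. The median of all probe sets was 0.13 as deposited and -0.15 after median scaling, and the split was 1278 higher and 1237 lower after quantile normalization and 999 higher and 1638 lower after median scaling. With the fluidics run as a block 1057 passed (585 higher, 472 lower), which links the groups only through the arrays at 3 g/L.

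**Figure D3:**
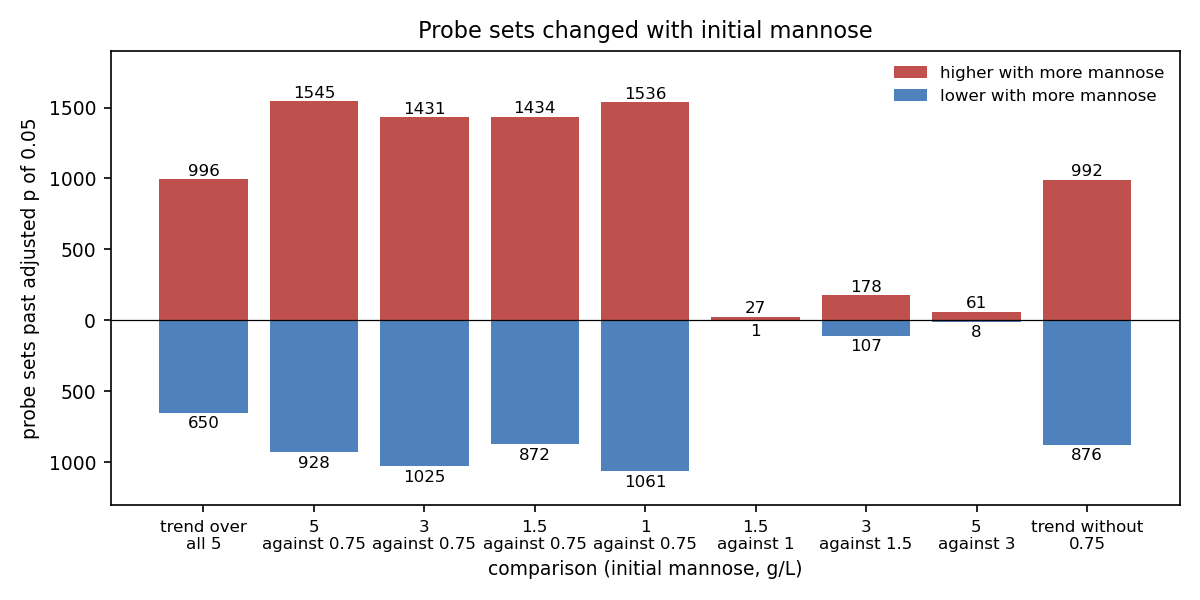
Probe sets higher (bars above zero) and lower (below zero) in each comparison at adjusted p < 0.05. The vertical axis is the number of 6956 tested probe sets and the numbers on the bars are the counts.

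All 35 ribosome biogenesis genes tested were higher at 5 than at 0.75 g/L (0 lower and 0 not passing, 35 and 0 adjusted over the list alone), by a median of 2.33, or 2.20 relative to the median of all probe sets (camera adjusted p = 1.57e-18). In trehalose and glycogen 14 of 17 were lower, 0 higher and 3 not passing (15 and 0 adjusted over the list alone; median -1.74, relative -1.87, 1.92e-11). In general stress 13 of 18 were lower, 1 higher and 4 not passing (13 and 1 adjusted over the list alone; median -1.27, relative -1.40, 9.18e-09). Amino acid synthesis had 26 of 41 higher, 2 lower and 13 not passing (29 and 2 adjusted over the list alone; median 0.66, relative 0.54, 0.000219), sulfur and methionine 13 of 20 higher, 0 lower and 7 not passing (14 and 0 adjusted over the list alone; median 0.66, relative 0.53, 0.00282). In the cell wall list 11 of 20 were lower, 1 higher and 8 not passing (14 and 2 adjusted over the list alone; median -0.56, relative -0.69, 0.00124). These 6 lists also passed with an estimated correlation.

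Glycolysis was lower, with 7 of 16 lower, 0 higher and 9 not passing (9 and 0 adjusted over the list alone). Its median was -0.39 (camera adjusted p = 0.000518, and adjusted p = 0.079 with an estimated correlation), but 0.13 with the fluidics run as a block. The TCA cycle had 8 of 21 lower, 1 higher and 12 not passing (10 and 1 adjusted over the list alone). Its median was -0.38 (0.00291, and adjusted p = 0.0867 with an estimated correlation). Ethanol and acetate had 4 of 15 lower, 1 higher and 10 not passing (4 and 1 adjusted over the list alone). The median was -0.33 (0.0156, and adjusted p = 0.079 with an estimated correlation). The pentose phosphate pathway had 5 of 10 lower, 1 higher and 4 not passing (6 and 1 adjusted over the list alone). Its median was -0.55 (0.0156, and adjusted p = 0.0851 with an estimated correlation).

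Of respiratory chain genes 26 of 29 did not pass, 1 was lower and 2 were higher (1 and 0 adjusted over the list alone). The list passed camera downward with a median of -0.21 (adjusted p = 0.0401, and adjusted p = 0.079 with an estimated correlation). Low oxygen had 3 of 8 lower, 1 higher and 4 not passing (3 and 1 adjusted over the list alone). Its median was -0.52 (0.0491, and adjusted p = 0.112 with an estimated correlation). After quantile normalization the TCA cycle, ethanol and acetate, pentose phosphate, respiratory chain and low-oxygen lists no longer passed. Cytosolic ribosomal protein genes were higher, 22 of 80, with 0 lower and 58 not passing (17 and 0 adjusted over the list alone). Their median was 0.28 (0.0123, and adjusted p = 0.605 with an estimated correlation), but 0.01 after median scaling, where they did not pass, and 0.63 with the run as a block.

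With the fluidics run as a block the medians of the other lists were 2.04 (ribosome biogenesis), -1.98 (trehalose and glycogen), -1.53 (general stress), 0.57 (amino acids), 0.37 (sulfur), -0.45 (cell wall), -0.56 (TCA cycle), -0.14 (ethanol and acetate), -0.56 (pentose phosphate), -0.14 (respiratory chain) and -0.55 (low oxygen). The last 4 and the cell wall list did not pass there.

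The other 13 lists did not pass at 5 against 0.75 g/L. Glyoxylate had 3 higher, 0 lower and 5 not passing (3 and 0 adjusted over the list alone, camera adjusted p = 0.052). GDP-mannose had 5, 3 and 20 (5 and 3 adjusted over the list alone, 0.117). N-glycosylation had 1, 2 and 19 (1 and 0 adjusted over the list alone, 0.117). The unfolded protein response had 1, 3 and 12 (1 and 3 adjusted over the list alone, 0.24). Iron uptake had 6, 1 and 4 (6 and 1 adjusted over the list alone, 0.187) and mating-type genes 3, 0 and 6 (3 and 0 adjusted over the list alone, 0.29). Glycerol had 1, 2 and 4 (1 and 2 adjusted over the list alone, 0.301) and galactose 0, 0 and 4 (0 and 0 adjusted over the list alone, 0.625). Hexose transport had 4, 3 and 3 (4 and 3 adjusted over the list alone, 0.788) and phosphate 3, 1 and 7 (3 and 1 adjusted over the list alone, 0.924). Ergosterol had 4, 3 and 16 (4 and 3 adjusted over the list alone, 0.798). Cell cycle had 5, 3 and 12 (5 and 3 adjusted over the list alone), with a median of 0.06 and a camera direction of down (0.706). Glucan and chitin had 8, 5 and 9 (9 and 5 adjusted over the list alone), with a median of 0.03 and a camera direction of down (0.924). After median scaling the medians of hexose transport, cell cycle, glucan and chitin and ergosterol changed sign, to -0.24, -0.21, -0.24 and -0.09.

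**Figure D4:**
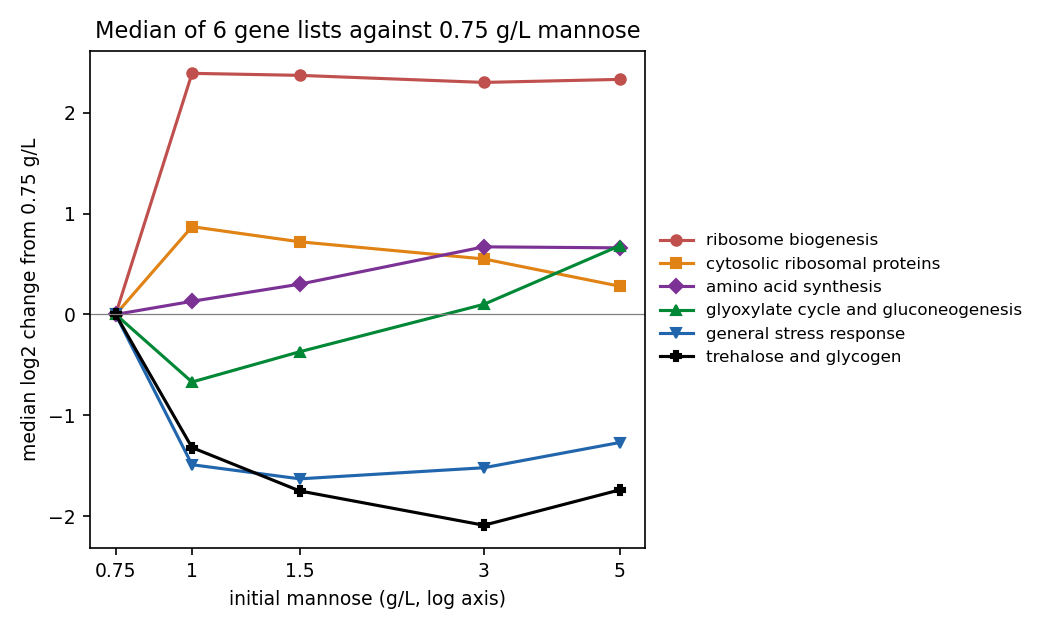
Median log2 change of the genes of 6 lists against 0.75 g/L (vertical axis) at each initial mannose concentration (horizontal axis, g/L). After median scaling the ribosomal protein median at 5 g/L was 0.01, glyoxylate at 3 g/L went from 0.10 to -0.14 (-0.15 after quantile normalization) and amino acid synthesis at 1 g/L from 0.13 to -0.07.

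At 3 against 0.75 g/L HXT1 rose at least 35.1-fold (5.56 ± 0.27, adjusted p = 7.1e-09), NSR1 at least 19.9-fold (5.13 ± 0.17, 3.18e-10) and ARX1 at least 4.91-fold (4.47 ± 0.35, 2.9e-07). COX26 fell at least 9.38-fold (-4.17 ± 0.29, 8.62e-08), RGI1 16.0-fold (-4.00 ± 0.20, 8.43e-09) and GPH1 15.1-fold (-3.92 ± 0.23, 2.58e-08). Lists were tested with camera here, and in the comparisons below, after the results were seen. Ribosome biogenesis was higher (35 of 35, 0 lower, 35 and 0 adjusted over the list alone, median 2.30, adjusted p = 7.92e-20). Amino acid synthesis had 31 higher, 1 lower and 9 not passing (33 and 2 adjusted over the list alone, median 0.67, 1.48e-05). Sulfur and methionine had 13 higher, 0 lower and 7 not passing (14 and 0 adjusted over the list alone, median 0.62, 0.00118). Trehalose and glycogen had 0 higher, 16 lower and 1 not passing (0 and 16 adjusted over the list alone, median -2.09, 5.77e-12). General stress had 0 higher, 14 lower and 4 not passing (0 and 14 adjusted over the list alone, median -1.52, 9.64e-11). The cell wall list had 2 higher, 9 lower and 9 not passing (2 and 9 adjusted over the list alone, median -0.25, 0.00351).

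Cytosolic ribosomal protein genes were also higher at 3 g/L, with 46 higher, 0 lower and 34 not passing (49 and 0 adjusted over the list alone). Their median was 0.55 (camera adjusted p = 1.83e-07, and adjusted p = 0.348 with an estimated correlation). The TCA cycle had 1 higher, 9 lower and 11 not passing (1 and 11 adjusted over the list alone). Its median was -0.37 (0.00547, and adjusted p = 0.132 with an estimated correlation). Ethanol and acetate had 1 higher, 6 lower and 8 not passing (1 and 6 adjusted over the list alone). The median was -0.32 (0.0247, and adjusted p = 0.0978 with an estimated correlation). Glycolysis had 0 higher, 5 lower and 11 not passing (0 and 6 adjusted over the list alone). Its median was -0.20 (0.0221, and adjusted p = 0.254 with an estimated correlation).

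Here 1431 probe sets were higher and 1025 lower (3043 at unadjusted p < 0.05), and 47.7% had no overlap where chance gives 10%. The split was 1210 higher and 1245 lower after quantile normalization and 936 and 1565 after median scaling. With the run as a block 1936 passed (1032 higher, 904 lower). Within run A the medians were 2.10 for ribosome biogenesis, 0.65 for amino acids, 0.50 for sulfur, 0.84 for ribosomal proteins, -2.25 for trehalose and glycogen and -1.59 for general stress. Medians there were -0.41 for the cell wall, -0.44 for the TCA cycle, -0.32 for ethanol and acetate and 0.11 for glycolysis (-0.2 over all arrays). Medians with the run as a block were the same.

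At 1.5 against 0.75 g/L NSR1 rose at least 19.5-fold (5.10 ± 0.17, adjusted p = 3.43e-10), BMT5, a 25S rRNA methyltransferase, at least 9.44-fold (4.06 ± 0.27, 9.25e-08) and ARX1 at least 4.2-fold (4.24 ± 0.35, 5.53e-07). TKL2, a transketolase isoform with 2 other probe sets, fell 16.8-fold (-4.07 ± 0.23, 3.37e-08). ALD3, an aldehyde dehydrogenase of stress, fell 14.7-fold (-3.87 ± 0.21, 2.98e-08) and HAB1 at least 3.58-fold (-3.86 ± 0.42, 6.54e-06). Ribosome biogenesis was higher (35 of 35, 0 lower, 35 and 0 adjusted over the list alone, median 2.37, camera adjusted p = 1.51e-20). General stress had 0 higher, 15 lower and 3 not passing (0 and 15 adjusted over the list alone, median -1.63, 1.48e-13). Trehalose and glycogen had 1 higher, 16 lower and 0 not passing (1 and 16 adjusted over the list alone, median -1.75, 5.45e-13). The cell wall list had 1 higher, 8 lower and 11 not passing (2 and 8 adjusted over the list alone, median -0.30, 0.000979).

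Cytosolic ribosomal protein genes had 57 higher, 0 lower and 23 not passing at 1.5 g/L (60 and 0 adjusted over the list alone). Their median was 0.72 (camera adjusted p = 1.27e-10, and adjusted p = 0.273 with an estimated correlation). Sulfur and methionine had 8 higher, 0 lower and 12 not passing (10 and 0 adjusted over the list alone). The median was 0.45 (0.00782, and adjusted p = 0.0565 with an estimated correlation). The TCA cycle had 0 higher, 11 lower and 10 not passing (0 and 12 adjusted over the list alone). Its median was -0.51 (0.000233, and adjusted p = 0.0617 with an estimated correlation). Glycolysis had 0 higher, 3 lower and 13 not passing (0 and 3 adjusted over the list alone). Its median was -0.07 (0.0452, and adjusted p = 0.279 with an estimated correlation).

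In this comparison 1434 probe sets were higher and 872 lower (2953 at unadjusted p < 0.05), and 46.6% had no overlap where chance gives 10%. The split was 1267 higher and 1065 lower after quantile normalization and 998 and 1335 after median scaling. With the run as a block 491 passed (247 higher, 244 lower) and with the hybridisation session as a block 786 (510 higher, 276 lower). No run held both groups, so the run block links them only through the arrays at 3 and 5 g/L. The errors of all genes named here grew with it, as for NSR1 (4.80 ± 0.42 there) and ARX1 (3.75 ± 0.93). The fall in calls therefore cannot be told apart from lost precision. With the run the medians were 2.15 for ribosome biogenesis, -1.55 for general stress, -2.04 for trehalose and glycogen, -0.43 for the cell wall and 0.96 for ribosomal proteins. They were 0.45 for sulfur, -0.59 for the TCA cycle and 0.18 for glycolysis, whose median changed sign. Over the trend and the comparisons without 1 g/L, 17 list results no longer passed with the run as a block.

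At 1 against 0.75 g/L NSR1 rose at least 17.0-fold (4.90 ± 0.17, adjusted p = 5.87e-10), BMT5 at least 8.87-fold (3.97 ± 0.27, 9.77e-08) and ARX1 at least 3.94-fold (4.15 ± 0.35, 6.67e-07). TKL2 fell 27.6-fold (-4.79 ± 0.23, 9.49e-09), FMP45, a SUR7 family membrane protein, 20.8-fold (-4.38 ± 0.25, 2.51e-08) and HAB1 at least 3.58-fold (-4.47 ± 0.42, 1.78e-06). Ribosome biogenesis was higher (35 of 35, 0 lower, 35 and 0 adjusted over the list alone, median 2.39, camera adjusted p = 3.36e-20). General stress had 1 higher, 14 lower and 3 not passing (1 and 15 adjusted over the list alone, median -1.49, 4.55e-12). Trehalose and glycogen had 1 higher, 15 lower and 1 not passing (1 and 16 adjusted over the list alone, median -1.32, 6.52e-10). The cell wall list had 1 higher, 9 lower and 10 not passing (1 and 9 adjusted over the list alone, median -0.37, 0.000481). Cytosolic ribosomal protein genes had 69 higher, 0 lower and 11 not passing (72 and 0 adjusted over the list alone). Their median was 0.87 (4.48e-14, and adjusted p = 0.181 with an estimated correlation). Sulfur and methionine had 10 higher, 0 lower and 10 not passing (11 and 0 adjusted over the list alone). The median was 0.44 (0.00715, and adjusted p = 0.054 with an estimated correlation). The cell cycle had 8 higher, 1 lower and 11 not passing (9 and 1 adjusted over the list alone). Its median was 0.51 (0.0325, and adjusted p = 0.202 with an estimated correlation).

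The TCA cycle was lower at 1 than at 0.75 g/L, with 0 higher, 8 lower and 13 not passing (0 and 9 adjusted over the list alone). Its median was -0.44 (camera adjusted p = 0.000297, and adjusted p = 0.0616 with an estimated correlation). Ethanol and acetate had 2 higher, 7 lower and 6 not passing (2 and 7 adjusted over the list alone). The median was -0.09 (0.0278, and adjusted p = 0.092 with an estimated correlation). The respiratory chain had 0 higher, 4 lower and 25 not passing (0 and 2 adjusted over the list alone). Its median was -0.13 (0.032, and adjusted p = 0.0616 with an estimated correlation). Glyoxylate had 0 higher, 5 lower and 3 not passing (0 and 5 adjusted over the list alone). Its median was -0.67 (0.0325, and adjusted p = 0.202 with an estimated correlation).

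In total 1536 probe sets were higher and 1061 lower at 1 than at 0.75 g/L (3236 at unadjusted p < 0.05), and 50.3% had no overlap where chance gives 10%. The split was 1342 higher and 1261 lower after quantile normalization and 1073 and 1558 after median scaling. No run held both groups. With the hybridisation session as a block 845 passed (548 higher, 297 lower), and with the fluidics station as a block 1514 (833 higher, 681 lower). The other lists of these 3 comparisons did not pass. Among them median, mean and camera direction differed in sign for hexose transport, N-glycosylation, the unfolded protein response, glucan and chitin, pentose phosphate, phosphate, iron and mating-type genes in at least 1 comparison.

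Between 1 and 1.5 g/L the vitamin B6 genes changed most, SNO1 rising 5.90-fold (2.56 ± 0.18, n = 3 and 3, adjusted p = 3.49e-06) and SNZ1 5.52-fold (2.46 ± 0.14, 4.1e-07). CIT3, a mitochondrial citrate synthase, passed (0.000112) with both groups within background. PUT4, the proline permease, fell 2.15-fold (-1.11 ± 0.21, 0.0349), and did not pass in 14 of 29 other settings. No run or fluidics station held both groups, so these arrays alone cannot set mannose apart from either. Of 28 probe sets, 27 were higher and 1 lower (769 at unadjusted p < 0.05). With the station as a block 12 passed, with only the 6 arrays compared 3, and a per-gene test without moderation gave 0. No overlap was found for 15.6%, where chance gives 10% for independent arrays. Amino acid synthesis was higher (1 higher, 0 lower and 40 not passing, 4 and 0 adjusted over the list alone; median 0.21, camera adjusted p = 7.36e-05). Trehalose and glycogen were lower (0 higher, 0 lower and 17 not passing, 0 and 5 adjusted over the list alone; -0.37, 1.68e-06, and adjusted p = 0.0913 with an estimated correlation), as were cytosolic ribosomal protein genes (0 higher, 0 lower and 80 not passing, 0 and 0 adjusted over the list alone; -0.18, 7.36e-05, and adjusted p = 0.587 with an estimated correlation), which did not pass after quantile normalization (-0.08).

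Between 1.5 and 3 g/L the mitotic and wall genes CLB1 (3.13-fold, -1.64 ± 0.17, adjusted p = 0.000112) and CWP1 (3.72-fold, -1.90 ± 0.14, 8.59e-06) fell, with COX26 (at least 1.82-fold, -1.81 ± 0.29, 0.00267). DAK2 rose 8.81-fold (3.14 ± 0.36, 0.00022), GID10, a receptor of the GID ubiquitin ligase, at least 2.60-fold (3.61 ± 0.42, 0.00025) and UBC11 at least 2.41-fold (4.01 ± 0.28, 8.59e-06). Amino acid synthesis had 3 higher, 0 lower and 38 not passing (3 and 0 adjusted over the list alone, median 0.30, camera adjusted p = 2.14e-08). Glyoxylate had 1 higher, 0 lower and 7 not passing (4 and 0 adjusted over the list alone). Its median was 0.69 (0.000198, and adjusted p = 0.118 with an estimated correlation). The cell cycle had 0 higher, 1 lower and 19 not passing (0 and 1 adjusted over the list alone). Its median was -0.24 (0.0127, and adjusted p = 0.326 with an estimated correlation). Cytosolic ribosomal protein genes had 0 higher, 0 lower and 80 not passing (0 and 0 adjusted over the list alone). Their median was -0.18 (0.0127, and adjusted p = 0.644 with an estimated correlation). GDP-mannose had 0 higher, 1 lower and 27 not passing (0 and 1 adjusted over the list alone). The median was -0.21 (0.0244, and adjusted p = 0.605 with an estimated correlation).

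Of 285 probe sets 178 were higher and 107 lower at 3 than at 1.5 g/L (1351 at unadjusted p < 0.05), and 23.6% had no overlap where chance gives 10%. The split was 193 higher and 177 lower after quantile normalization and 163 and 160 after median scaling. No run held both groups, so the run block links them only through the arrays at 5 g/L. With the run as a block limma called 0 (577 at unadjusted p < 0.05). The changes of the genes named were UBC11 (3.79 ± 0.57), GID10 (3.71 ± 0.87), DAK2 (3.22 ± 0.70), CWP1 (-1.67 ± 0.28), COX26 (-2.41 ± 0.37) and CLB1 (-1.56 ± 0.33) there. The medians there were 0.41 for amino acids, 0.64 for glyoxylate, -0.31 for the cell cycle, -0.22 for ribosomal proteins and -0.13 for GDP-mannose.

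Between 3 and 5 g/L, GRE1, a hydrophilin of stress, rose 9.03-fold (3.18 ± 0.18, adjusted p = 6.09e-07), SPS100, a spore wall protein, at least 4.68-fold (2.84 ± 0.43, 0.00458) and YCL048W-A at least 3.38-fold (3.18 ± 0.60, 0.0266). WSC4 fell 1.85-fold (-0.89 ± 0.15, 0.0151) and SFG1, a factor of filamentous growth, at least 1.31-fold (-0.98 ± 0.20, 0.0409). NPL3, an RNA-binding protein with 2 other probe sets, fell 3.04-fold (-1.61 ± 0.35, 0.0489). These falls did not pass in 10 of 30, 20 of 29 and 25 of 30 other settings, and YCL048W-A did not in 10 of 29. With the run as a block SPS100 (2.87 ± 0.48), YCL048W-A (2.22 ± 0.38), WSC4 (-0.93 ± 0.20), SFG1 (-0.81 ± 0.23) and NPL3 (-1.80 ± 0.46) did not pass. General stress had 5 higher, 0 lower and 13 not passing (10 and 0 adjusted over the list alone, median 0.50, camera adjusted p = 4.19e-09). Glyoxylate had 3 higher, 0 lower and 5 not passing (5 and 0 adjusted over the list alone, median 0.89, 1.61e-07).

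None of 80 ribosomal protein, 16 glycolysis, 17 trehalose and glycogen and 20 cell cycle genes passed at 5 against 3 g/L, also when adjusted over the list alone. Ribosomal proteins shifted by -0.22 (camera adjusted p = 3.79e-15, and adjusted p = 0.316 with an estimated correlation). Glycolysis shifted by -0.21 (0.00833, and adjusted p = 0.316 with an estimated correlation), but by -0.02 after quantile normalization, where it did not pass. The cell cycle shifted by -0.12 (0.0271, and adjusted p = 0.316 with an estimated correlation). Trehalose and glycogen shifted by 0.30 (0.00833, and adjusted p = 0.316 with an estimated correlation).

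Of 69 probe sets, 61 were higher and 8 lower at 5 than at 3 g/L (650 at unadjusted p < 0.05). No overlap was found for 14.2%, where chance gives 10% for independent arrays. With the run as a block 13 passed (13 higher, 0 lower). Within run B, with 2 and 2 arrays, 2 did (512 at unadjusted p < 0.05). Within run B the medians were 0.52 for general stress, 0.72 for glyoxylate, 0.20 for trehalose and glycogen, -0.14 for ribosomal proteins, -0.08 for glycolysis and -0.15 for the cell cycle. Medians with the run as a block were the same. In run C, with 1 array at 5 and 3 at 1.5 g/L, the medians of 5 against 1.5 g/L were 0.57 for general stress and 1.36 for glyoxylate.

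Among the 5 concentrations 3241 probe sets differed (3762 at unadjusted p < 0.05), of which 1464 also followed the trend and 1777 did not, and 182 followed the trend alone. Those with the smallest adjusted p outside the trend had low or high points in the middle. EGO4 went from 1517 ± 84.3 at 0.75 g/L through 196 ± 17.5, 160 ± 25.8 and 112 ± 2.4 to 302 ± 12.5 (SD, n = 3; adjusted p = 3.55e-09), and YNL194C, of the SUR7 family, from 449 ± 31.1 through 27.4 ± 3.5, 41.5 ± 4.7 and 51.0 ± 10.1 to 108 ± 19.6 (1.31e-08). GRE1 was 93.9 ± 6.4 at 0.75 g/L, 16.1 ± 3.5 at 1 g/L and 262 ± 31.6 at 5 g/L (4.56e-09), and TKL2 416 ± 93.0, 15.0 ± 2.9 and 243 ± 21.1 (1.07e-08). SRP40, a nucleolar chaperone, rose from 25.7 ± 3.9 at 0.75 g/L to 208 ± 27.4 at 1 and 229 ± 6.6 at 1.5 g/L and was 146 ± 9.6 at 5 g/L (1.3e-08).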

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

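Signals near background limit dim genes, 3 arrays limit precision, and the fluidics runs nearly follow the groups. Main values are in brackets. With the fluidics run as a block the trend had 875 (1646), 5 against 0.75 g/L 1057 (2473), 1.5 against 0.75 g/L 491 (2306), 3 against 1.5 g/L 0 (285), 5 against 3 g/L 13 (69) and 8 lists (13) at 5 against 0.75 g/L. The cytosolic ribosomal protein trend passed upward there (camera adjusted p = 0.00631, and over 34 settings 1.57e-13, downward without 0.75 g/L, to 0.978). Of 178 named gene results 48 no longer passed there. The 178 include genes that had not passed before. They also include results for any difference and with 1 g/L, whose fits hardly changed (correlation within runs -0.008). The share lost among results that could lose the call was therefore larger. With the session as a block 1.5 against 0.75 g/L had 786, 1 against 0.75 g/L 845 (2597), 3 against 1.5 g/L 11 and 5 against 3 g/L 24, and with the station 1 against 0.75 g/L 1514, 1.5 against 1 g/L 12 (28) and the ribosomal protein list at 3 against 1.5 g/L turned upward (adjusted p = 0.498). Within runs 3 against 0.75 g/L had 1394 (2456) and 5 against 3 g/L 2. The replicate block left 33 at 5 against 3 g/L and no filter left 40. At 1.5 against 1 g/L quantile normalization gave 60, the stricter filter 72, and eBayes with trend and robust 65, and quantile normalization left 8 lists at 5 against 0.75 g/L. With only the 6 arrays compared, 1.5 against 1 g/L had 3, 3 against 1.5 g/L 97 and 5 against 3 g/L 38, and a per-gene test without moderation gave 0 (630 at unadjusted p < 0.05), 10 and 6. An estimated correlation left 0 lists for the trend (9) and 6 at 5 against 0.75 g/L, 6 at 3 (10), 4 at 1.5 (8) and 4 at 1 against 0.75 g/L (11), 1 at 1.5 against 1 g/L (3), 1 at 3 against 1.5 g/L (5), 2 at 5 against 3 g/L (6) and 0 for the trend without 0.75 g/L (8). The stricter filter left 7 lists at 1 against 0.75 g/L and 2 at 3 against 1.5 g/L, where the run block left 3, the session block 2 and leaving out 1.5 g/L replicate 2 left 3. Without 3 g/L the trend had 832 and without 5 g/L 868, there with ribosomal proteins upward (adjusted p = 0.00954). Without 0.75 g/L the ribosome biogenesis (adjusted p = 0.387, 6.94e-11 to 0.688 over 34 settings), general stress (0.024, 3.38e-05 to 0.155) and RNA polymerase III (0.946) trends changed sign, as did RPS14B (-0.22) and RPS26B (-0.23). Without the 5 arrays whose records were not completed ribosome biogenesis (0.688), general stress (0.0371), RPS14B (-0.21) and GAL4 (-0.32) did, glycolysis at 5 against 3 g/L did (0.459, 0.00029 to 0.688 over 29 settings), 3 against 1.5 g/L had 91 and 5 against 3 g/L 10. Leaving out 1 array moved 3 against 1.5 g/L to 105 to 275, with 167 without 1.5 g/L replicate 1, 105 without 1.5 g/L replicate 3 and 158, 127 and 164 without 3 g/L replicates 1, 2 and 3, and its ribosomal protein list to adjusted p of 4.16e-09 (without 3 g/L replicate 1) to 0.963, upward, without 3 g/L replicate 3. It moved 5 against 3 g/L to 24 to 60, with 40, 36 and 44 without the 0.75 g/L replicates 1, 2 and 3, 43 and 45 without 1 g/L replicates 2 and 3, 26, 29 and 42 without the 3 g/L and 38, 28 and 24 without the 5 g/L replicates 1, 2 and 3. The other counts of probe sets and lists stayed within 1.5 times. The cause of these differences was not tested.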

Other observations

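Of 10 further lists, written after the main results were seen, when PRM5, SPS1, SPS100, SNO1, SNZ1 and PUT4 were known to change, the pheromone response list had the largest median rise with mannose. It held PRM5, and mating-type-specific genes were also known to rise, so its camera calls cannot be set apart from that choice. The list was not tested without PRM5. AGA1, the anchorage subunit of a-agglutinin, rose from 30.0 ± 3.9 (SD, n = 3) at 0.75 g/L to 302 ± 51.0 at 5 g/L (1.24 ± 0.07 log2 per doubling, limma adjusted p = 9.1e-09), and PRM1, a membrane fusion protein, from 8.6 ± 1.3, within background, to 82.0 ± 7.5 (1.28e-08). FUS1, of cell fusion, rose from 4.9 ± 1.1, within background, to 25.1 ± 4.7 (9.6e-07). Of 11 genes 8 rose, PRM5 among them, 0 fell and 3 did not pass (10 and 0 adjusted over the list alone), with a median of 0.86 (camera adjusted p = 1.76e-10), 0.81 without 0.75 g/L (2.29e-11) and 0.94 with the fluidics run as a block. At 5 against 3 g/L the list was higher by 0.47 (9.92e-05), with PRM4 24 ± 0.8 at 3 and 59.8 ± 6.0 at 5 g/L. Mitochondrial ribosomal protein genes fell, 37 of 54, with 0 higher and 17 not passing (43 and 0 adjusted over the list alone). Their median was -0.24 (camera adjusted p = 2.39e-17), and -0.32 with the run as a block.

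The carnitine genes YAT1 and YAT2, acetyltransferases, had their lowest signal at 1 g/L (51.3 ± 10.1 and 25.6 ± 7.1) and their highest at 5 g/L (790 ± 68.6 and 235 ± 10.4, trend adjusted p = 6.79e-07 and 0.000725). CAT2, another, went from 107 ± 5.8 at 0.75 g/L through 23.8 ± 2.7 at 1 g/L to 75.0 ± 2.5. The fatty acid oxidation and carnitine list had 5 higher, 1 lower and 9 not passing of 15 for the trend (5 and 1 adjusted over the list alone, camera adjusted p = 0.0758). It was lower at 1 than at 0.75 g/L (median -0.66, 0.00616, and adjusted p = 0.117 with an estimated correlation) and higher at 5 than at 3 g/L (0.52, 6.39e-06).

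RNA polymerase III subunits rose in the trend, with 6 of 12 higher and 0 lower (7 and 0 adjusted over the list alone). Their median was 0.33 (camera adjusted p = 0.00591, and adjusted p = 0.327 with an estimated correlation). Aminoacyl-tRNA synthetases had 8 of 18 higher and 0 lower (8 and 0 adjusted over the list alone). Their median was 0.18 (0.00591, and adjusted p = 0.327 with an estimated correlation). Without 0.75 g/L the 2 lists did not pass, with 1 higher and 1 lower for RNA polymerase III (1 and 1 adjusted over the list alone, median 0.00, camera adjusted p = 0.946) and 1 and 2 for the synthetases (0 and 0 adjusted over the list alone, median 0.00, 0.827). THI4, of thiamine synthesis, rose from 25.7 ± 4.5 to 92.5 ± 14.6 (adjusted p = 0.000199). Thiamine and pyridoxine had 5 of 13 higher and 0 lower (5 and 0 adjusted over the list alone). Their median was 0.06, or -0.02 after median scaling (0.0108, and adjusted p = 0.0585 with an estimated correlation), and SNO1 and SNZ1, already known to change, were among the 5, so the call cannot be set apart from that choice. Of 3 tested histone genes 1 was lower and 0 higher (2 and 0 adjusted over the list alone), with a median of -0.22 (0.0296, and adjusted p = 0.188 with an estimated correlation). The histone list did not pass after quantile normalization (-0.19, camera adjusted p = 0.0552). The proteasome (0 of 31 higher, 1 lower, 0 and 1 adjusted over the list alone, 0.368) and nitrogen lists (1 of 19 higher, 5 lower, 1 and 5 adjusted over the list alone, 0.121) did not pass. The sporulation list, with 4 of 14 genes tested, held SPS1 and SPS100, already known to change, so its camera calls cannot be set apart from that choice. They were a median of 0.54 for the trend (2 higher, 0 lower, 2 and 0 adjusted over the list alone, 0.0386, and adjusted p = 0.184 with an estimated correlation), 0.86 without 0.75 g/L (3 and 0, 3 and 0 adjusted over the list alone, 0.0122) and 1.22 at 5 against 3 g/L (1 and 0, 2 and 0 adjusted over the list alone, 0.000485). The other 2 genes, IME1 and NDT80, regulators of meiosis, did not pass in the trend (0.116 and 0.939), and without 0.75 g/L IME1 did (0.0283).

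All tests of this part were chosen after the main results were seen, that of slower growth at 0.75 g/L before the values of its list were. The 0.75 g/L arrays stood apart from the other 12, with lower ribosome biogenesis and higher stress and storage genes. A cause in the fluidics station is argued against by a ribosome biogenesis median of 2.22 at 3 against 0.75 g/L with the station as a block, and one in the hybridisation session by the design, since these 6 arrays share a session. A cause in a constant factor for each array is argued against by the ribosome biogenesis median of 2.05 at 5 against 0.75 g/L after median scaling. Median scaling moves all probe sets of an array alike, so it does not test differences that depend on the signal. The 1 array at 3 g/L of run A, replicate 1, lay 2.39 above the median of the 0.75 g/L arrays of that run. This speaks against the run but leaves it open. It rests on 1 array, which stood apart from the others in control signals and in correlation with its replicates. Slower growth at 0.75 g/L may be a reason. RNA polymerase III subunits had a median of 1.12 at 1 against 0.75 g/L (11 of 12 higher, camera adjusted p = 0.000143). Ribosome biogenesis had already been seen higher there, so this value cannot tell slower growth from other causes that would lower both lists. Growth was not analysed here, so this stays open.

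The general stress list was higher at 5 than at 3 g/L, though lower than at 0.75 g/L. This could come from the array 3 g/L replicate 1, which is argued against by a median of 0.51 without it. It could also come from the fluidics run, argued against by 0.52 with the run as a block. That value is the difference within run B and rests on 2 arrays at 3 and 2 at 5 g/L, 1 of the latter with a record not completed. Less glucose left at 5 g/L may be another reason, for which genes known to rise at low glucose had a median of -0.26 between 3 and 5 g/L (HXT2 -0.21, HXT4 -0.37, HXT6 -0.44, HXT7 -0.31, SUC2 -0.20 and HXK1 0.39). None of these passed, and the residual glucose was not analysed here, so this stays open. Of the signs of RNA quality the 3'/5' ratio of SPT15 was 3.69 to 3.98 at 3 g/L and 4.44 to 6.90 at 5 g/L (4.19 to 5.26 at 0.75 g/L), that of ACT1 was 1.89 to 2.17 and 1.49 to 2.14 (1.86 to 2.36), and RNA quality was not tested.

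For the trend, 1 of 100 draws of the concentration labels, the real one, called as many probe sets (1646, highest other 409). For any difference it was also 1 (3241, highest other 1397), so chance can be excluded for both only if the arrays are independent, while those of a concentration share a sample code and the fluidics runs nearly follow the groups. For comparisons of 2 concentrations the 10 splits are too few. The real value and the highest other split were 2473 and 0 at 5 against 0.75 g/L, 2456 and 0 at 3 against 0.75 g/L, 2306 and 0 at 1.5 against 0.75 g/L. They were 2597 and 1 at 1 against 0.75 g/L, 28 and 1 at 1.5 against 1 g/L, 285 and 2 at 3 against 1.5 g/L and 69 and 1 at 5 against 3 g/L. Array 3 g/L replicate 1 had a CreX-3 control signal of 4021 (560 to 2120 on the others), a 25S rRNA control signal of 965 (9 to 343), a mean correlation of 0.960 with its replicates and -33.6 on the axis holding 7.4% of variance.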
